A study of Rattus norvegicus with 8 samples.

How the data were processed

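Total RNA was taken from homogenised rat kidney, and biotin-labelled sense-strand DNA targets were hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The authors deposited 1 table with an intensity per probe set for each of the 8 arrays, made with Affymetrix Expression Console and RMA per the submitters' processing notes. Their versions are not given in the sources used here. The deposited values ran from 17.3 to 6229 with medians between 34.1 and 34.7, and nearly equal quartiles, so they were read as linear intensity already normalized between arrays. The design fixed in advance assumed log2 values and said that linear values would be logged first, which was done with no pseudocount because no value was 0 or negative. Detection calls were not used here, and values near the lowest signals of the array limit the size of any fold that starts there.

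The table held 29870 probe sets. The platform's annotation named 18511 of them with 1 gene symbol and 575 with several genes, and 10784 are unnamed here. Symbols were looked up by Entrez identifier in the rat RefSeq gene table of assembly GRCr8, where 18394 matched and 0 changed. Only probe sets with 1 symbol were used. For the 291 genes with more than 1 probe set the one with the highest mean over all arrays was kept, which gave 18166 genes, and no filter on dim genes was applied. Every column of the table belonged to a labelled sample. No pair of arrays shared more than 1 identical value, so each was counted as a separate sample.

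Arrays were grouped by the tissue region in their labels, 4 cortex and 4 medulla, and numbered within each region in label order. The treatment label is the same on all 8, and no contrast of treatments was made. The regions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, Benjamini-Hochberg adjustment over all genes), and a gene was called at an adjusted p under 0.05 with a difference of at least 2-fold. For members adjusted over their list alone the adjusted p was used with no fold threshold. Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists. Within a region, each gene's range was its highest minus its lowest log2 value, a gene passed at a range of at least 1, and the overlap of the regions was set beside the number expected from independent lists. A list's median range was placed among 10000 random lists matched on mean expression in 20 bins. Each array's deviation is its log2 value minus the mean of its region. Figures were drawn with matplotlib 3.10.9.

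The design, the tests, the alternatives and 26 gene lists were fixed before the data were examined. The lists cover the proximal tubule, the proximal straight tubule, podocytes, the thick ascending limb, the distal convoluted and connecting tubule, collecting duct principal cells, intercalated cells, urea and osmolyte handling, endothelium, fibroblasts and extracellular matrix, tubular injury, fibrinogen and coagulation, stone matrix proteins, vitamin D and calcium handling, oxalate metabolism and transport, leukocytes, chemokines and inflammatory mediators, oxidative stress, glycolysis and hypoxia, fatty acid oxidation, urothelium, adipocytes, erythrocytes, skeletal muscle, adrenal cortex and proliferation. Of 339 list entries, 300 were measured. The named genes were the 10 largest rises and falls among called genes without overlap of the regions (there were 0), up to 4 members per list with the smallest adjusted p, the 10 genes with the largest smaller regional range, and Fga, Fgb, Fgg, Spp1, Havcr1, Lcn2, Umod and Cyp24a1 always. This gave 115 genes, of which the text names those that illustrate a list, and genes chosen after their values were seen are said to be so. Slc12a1, Fn1, Slc8a1, Vdr and Top2a are among the 115.

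The alternatives were quantile normalization of the deposited values, median centring, the mean of a gene's probe sets, leaving out genes up to the 30th percentile of mean signal, each array left out in turn, limma with a trended robust prior, array weights, limma's treat against a 1.5-fold change, an adjusted p under 0.01, the adjusted p alone, a 2-fold difference with no test, 1.5-fold and 3-fold ranges, and camera on ranks or with an estimated correlation. Residual components as covariates, and both replicate 4 arrays left out, were added after the data were seen. The pipeline was tested on simulated data for medulla against cortex, with 18166 genes at the real means and within-region spreads, in which 66 genes each were changed by 1, 2 or 3 log2 units. It called 53% of the genes changed by 1 log2 unit, 98.5% of those changed by 2 and 100% of those changed by 3, and 0 unchanged genes, though 16 unchanged genes passed the adjusted p alone. A change of 1 log2 unit equals the fold threshold, and 92.4% of those genes passed the adjusted p alone. The changed genes were drawn at random from all genes, so these shares may differ for genes with a wider spread. The simulated arrays vary independently from gene to gene, unlike the real ones. For 4 against 4 arrays, an exact permutation test of a single gene cannot give a two-sided p below 0.0286.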

Results

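Gene expression was measured in kidney tissue of ten-week-old male Wistar rats on Affymetrix whole-transcript microarrays. Every sample carries the same treatment label, daily ethylene glycol with vitamin D on alternate days over 1 week. Ethylene glycol is metabolised to oxalate, and its combination with vitamin D is used to produce calcium oxalate crystals in rat kidney. The samples fall into 2 groups by tissue region, 4 arrays of cortex and 4 of medulla. The array medians lay between 34.1 and 34.7 intensity units, and the number of arrays limits the precision. Because the treatment label is shared, no treated against untreated comparison was made. The labels name no separate animals, so p-values measure only the spread between these arrays, which may be technical.

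The region labels allow 1 comparison, medulla against cortex, which asks how the tissue of the regions differed. Taken as lists, genes of urea and osmolyte handling were higher in medulla and genes of the proximal tubule lower, with a correlation between genes preset for the test. Neither list was called otherwise, with adjusted p = 0.589 with an estimated correlation for both. Slc14a2, the urea transporter of the inner medullary collecting duct, stood at 6.70 ± 0.53 (SD, n = 4) log2 intensity in medulla and 5.17 ± 0.49 (SD, n = 4) in cortex, a difference of 1.53 with a standard error of 0.32. Slc5a3, which imports myo-inositol, differed by 1.04 ± 0.29 (SE), Akr1b1, the aldose reductase that makes sorbitol, by 1.15 ± 0.43, and Nfat5, the transcription factor of the hypertonic response, by 0.78 ± 0.24. Slc22a8, an organic anion transporter of the proximal tubule, was 9.60 ± 0.40 (SD, n = 4) in cortex and 9.01 ± 0.30 (SD, n = 4) in medulla, a difference of -0.59 with a standard error of 0.22. Without medulla replicate 1 the Akr1b1 difference was 0.73, under 2-fold. None of these genes passed the test over all genes, with limma's adjusted p at 0.875 for each.

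Over all 18166 genes, limma with Benjamini-Hochberg adjustment called 0 genes, 0 higher and 0 lower, and the smallest adjusted p was 0.875. An unadjusted p under 0.05 was reached by 971 genes against 908 expected by chance, 503 of them higher in medulla and 468 lower. limma with a trended robust prior, limma with array weights and limma's test against a 1.5-fold change also called 0. In 515 genes, 2.83% of those tested, the 4 medulla values all lay on 1 side of the 4 cortex values, and chance gives 2.86%. Of these, 4 had a difference of at least 2-fold, all higher in medulla. They were Slc14a2, the urothelial surface antigen gene Psca with a difference of 1.34 ± 0.43 (SE), the cornified envelope gene Sprr1a with 1.37 ± 0.27, and Nrip3 with 1.05 ± 0.49. Sprr1a and Nrip3 were chosen after their values were seen. Without medulla replicate 1 the difference was 0.90 for Psca and 0.52 for Nrip3, both under 2-fold, and 1.30 for Slc14a2 and 1.16 for Sprr1a. With a 2-fold difference of means and no test, 16 genes passed, all higher in medulla.

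Gene lists fixed in advance were tested too. By camera with a preset correlation between genes of 0.01, 11 of 26 lists passed an adjusted p of 0.05. With an estimated correlation 0 of the 26 passed, and adjusted p = 0.589 for each of these 11. The urea and osmolyte list was higher in medulla (adjusted p = 2.08e-05, adjusted p = 0.589 with an estimated correlation), with a positive difference in 10 of 10 measured genes. Arrays of a region differed in this list, whose mean deviation was highest in cortex on replicate 1, at 0.375, and lowest in medulla on replicate 2, at -0.254. Adjusted over the list alone, 3 of its genes passed the adjusted p, all higher, against 0 over all genes tested. They were Slc14a2 and Slc5a3, which also reached 2-fold, and Nfat5, which did not. Slc5a3 and Nfat5 overlapped between the regions, at 8.12 and 8.54 on cortex replicate 1 against 7.92 and 8.34 on medulla replicate 2. By the exact permutation test the unadjusted p was 0.0571 for each of them and 0.0286 for Slc14a2. The urothelium list was also higher (adjusted p = 0.000802, and 0.589 as the adjusted p with an estimated correlation), with 7 of 7 genes positive, among them Psca and the uroplakin gene Upk1a, at 0.43 ± 0.19 (SE), or 0.28 without medulla replicate 1. Much of this rise lay on medulla replicate 1, where the mean deviation of the urothelium list from the mean of the medulla arrays was 0.56, against -0.22, -0.11 and -0.23 on the other medulla arrays. Psca measured 7.53 on it against 5.36 to 6.20 on the others. None of its 7 genes was called over all genes or adjusted over the list alone. These lists and the proximal tubule list passed with any 1 array left out.

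With the preset correlation only, 4 lists of stromal, vascular, injury and leukocyte genes were higher in medulla, and for each adjusted p = 0.589 with an estimated correlation. Each of the 4 also lost its call when single arrays were left out, as given below. The fibroblast and extracellular matrix list had 10 of 12 genes positive (adjusted p = 0.0028), including the pericyte receptor gene Pdgfrb at 0.43 ± 0.14 (SE) and the proteoglycan gene Bgn at 0.55 ± 0.32, or 0.34 without medulla replicate 4. The endothelium list had 8 of 9 positive (adjusted p = 0.00693), including the endothelial cadherin gene Cdh5 at 0.38 ± 0.15 and the vasa recta urea transporter gene Slc14a1 at 1.03 ± 0.44. The tubular injury list had 15 of 19 positive (adjusted p = 0.0237), including S100a6 at 0.92 ± 0.39 and the galectin gene Lgals3 at 0.55 ± 0.26. The leukocyte list had 11 of 19 positive (adjusted p = 0.0403), including the lysozyme gene Lyz2 at 0.69 ± 0.34. None of the genes of these 4 lists was called over all genes or adjusted over the list alone. Without medulla replicate 4 the adjusted p was 0.0618 for fibroblasts, 0.748 for tubular injury and 0.556 for leukocytes. Without cortex replicate 3 it was 0.0617, 0.067 and 0.278 for these lists. Without cortex replicate 2 it was 0.0995 for tubular injury and for leukocytes, without cortex replicate 1 it was 0.119 for tubular injury, and without medulla replicate 3 it was 0.0729 for leukocytes. The endothelium list had an adjusted p of 0.25 without cortex replicate 4 and of 0.0638 without medulla replicate 1.

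With the preset correlation only, 5 lists of cortical nephron segments and of metabolism were lower in medulla, and for each adjusted p = 0.589 with an estimated correlation. Except for the proximal tubule, each of them also lost its call when single arrays were left out. In the proximal tubule list 22 of 22 genes had a negative difference (adjusted p = 0.000495), with the endocytic receptor gene Lrp2 at -0.17 ± 0.08 (SE). The distal convoluted and connecting tubule list was negative in 9 of 9 (adjusted p = 0.0383), with the thiazide-sensitive cotransporter gene Slc12a3 at -0.49 ± 0.34 and the kallikrein gene Klk1 at -0.93 ± 0.70. The podocyte list, of the glomerular filter, was negative in 6 of 9 (adjusted p = 0.0403), with the slit diaphragm gene Nphs1 at -0.55 ± 0.24 and Clic5 at -0.50 ± 0.20. The oxalate metabolism and transport list was negative in 11 of 12 (adjusted p = 0.0107), with Agxt2 at -0.25 ± 0.12 and Prodh2 at -0.47 ± 0.24. The fatty acid oxidation list was negative in 11 of 12 (adjusted p = 0.0344), with the mitochondrial thiolase gene Hadhb at -0.17 ± 0.07. None of the genes of these 5 lists was called over all genes or adjusted over the list alone. Without medulla replicate 4 the differences were -0.095 for Lrp2, -0.27 for Slc12a3, -0.55 for Klk1, -0.17 for Agxt2 and -0.31 for Prodh2. Slc12a3 also stood at -0.29 without cortex replicate 3, and Klk1 at -1.51 without medulla replicate 2. Without medulla replicate 4 the adjusted p was 0.192 for the distal list, 0.219 for podocytes and for fatty acid oxidation, and 0.0618 for oxalate metabolism. Without cortex replicate 3 it was 0.267 for the distal list, 0.0788 for podocytes and 0.13 for fatty acid oxidation. Without cortex replicate 2 it was 0.0995 for the distal list and podocytes and 0.0538 for fatty acid oxidation, and without medulla replicate 1 these 3 stood at 0.19, 0.0816 and 0.0638. Without medulla replicate 3 it was 0.0684 for podocytes. In the list of the proximal straight tubule, which did not pass itself (adjusted p = 0.143), the lactate transporter gene Slc5a8 differed by -0.35 ± 0.09 and was the 1 gene lower in medulla to pass the adjusted p when adjusted over the list alone, without reaching 2-fold.

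**Figure D1:**
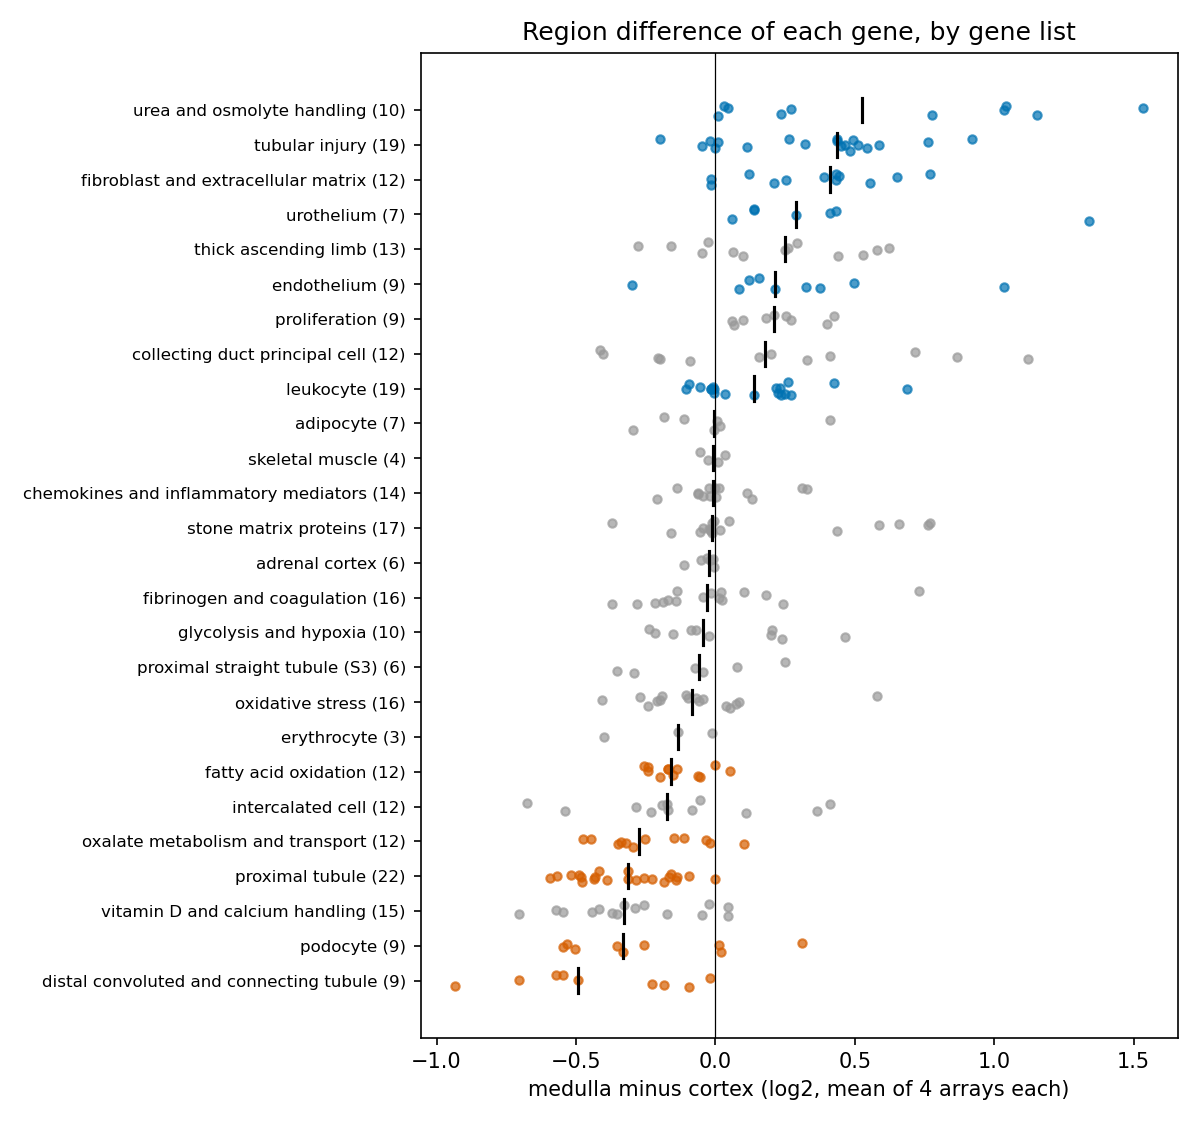
Difference between the mean of 4 medulla arrays and the mean of 4 cortex arrays (log2, horizontal axis) for each measured gene, 1 point per gene, by gene list (vertical axis, number of measured genes in brackets), with a black bar at each list's median. Blue lists were called higher and orange lists lower in medulla by camera with the preset correlation, grey lists were not called, and the urea and osmolyte list has all 10 genes to the right of 0.

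The other lists did not pass. Their adjusted p by camera was 0.0703 for vitamin D and calcium handling, 0.131 for the thick ascending limb, 0.137 for proliferation, 0.158 for intercalated cells, 0.343 for oxidative stress, 0.384 for adrenal cortex, 0.393 for collecting duct principal cells and 0.445 for adipocytes. It was 0.471 for fibrinogen and coagulation, 0.582 for erythrocytes, 0.72 for stone matrix proteins, 0.793 for chemokines and inflammatory mediators, 0.809 for skeletal muscle and 0.905 for glycolysis and hypoxia. The stone matrix list and the glycolysis list tested upward with medians of -0.01 and -0.05, and the chemokine list tested downward with a mean of 0.02. The number of called lists was 6 without cortex replicate 2, 5 without cortex replicate 3 and 6 without medulla replicate 4, against 11 with all arrays.

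The genes that the series title points to did not separate the regions. Fga, Fgb and Fgg encode the 3 chains of fibrinogen and lie next to each other on the same chromosome in the rat RefSeq table. On the array they are measured by probe sets 17739348, 17748274 and 17739336. Their medulla minus cortex differences were -0.14 ± 1.25 (SE), 0.01 ± 1.37 and 0.24 ± 0.99, all smaller than their standard errors, and each sign turned under some left-out arrays, with Fga between -1.07 and 0.83. The injury gene Havcr1 differed by 0.27 ± 2.00, osteopontin (Spp1) by 0.76 ± 0.67 (0.40 without medulla replicate 4 and 1.28 without cortex replicate 4), lipocalin Lcn2 by 0.11 ± 0.28, uromodulin (Umod) by -0.16 ± 0.35, and Cyp24a1, the vitamin D 24-hydroxylase, by -0.35 ± 1.67. limma's adjusted p for these 8 genes lay between 0.895 and 1. The standard errors were wide because arrays of the same region differed, which is the second comparison.

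Within each region, genes that differed at least 2-fold between arrays were counted, since the design text selects on a 2-fold change within cortex and within medulla and keeps genes found in both, and the labels do not say which arrays were set against which. The fibrinogen chains were among the most variable genes of both regions. Fga measured 5.75, 6.00, 6.61 and 10.01 log2 intensity on cortex replicates 1 to 4 and 5.36, 5.66, 7.04 and 9.75 on medulla replicates 1 to 4, a range of 19.1-fold in cortex and 21.0-fold in medulla. Fgb ranged over 28.5-fold in cortex and 23.4-fold in medulla, with its highest values, 9.89 and 9.59, on cortex replicate 4 and medulla replicate 4. Fgg had its highest values, 7.64 and 7.86, on those arrays too, against 4.46 to 4.77 on the other cortex arrays and 4.48 to 5.49 on the other medulla arrays. The lowest Fgg values lay about the lower quartile of all probe sets, 21.8 to 22.3 intensity units, so that its ranges are lower limits. Without cortex replicate 4 the cortex ranges were 0.86 log2 for Fga, 1.08 for Fgb and 0.31 for Fgg, against 4.26, 4.83 and 3.18 with it. Without medulla replicate 4 the medulla ranges were 1.69, 1.48 and 1.01, against 4.39, 4.55 and 3.38.

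Havcr1, which encodes kidney injury molecule 1, had the widest range of all genes in both regions. It measured 4.59, 5.15, 7.54 and 11.27 on the cortex arrays and 4.54, 4.80, 8.95 and 11.32 on the medulla arrays, a range of at least 102-fold and 110-fold, since its lowest values too lay close to the lower quartile of all probe sets. Without the replicate 4 array its ranges were 2.94 log2 in cortex and 4.41 in medulla. Cyp24a1 came next, with 5.42, 6.21, 10.18 and 10.65 in cortex and 5.31, 5.69, 10.08 and 9.97 in medulla. The apical calcium channel gene Trpv5 measured 5.47, 6.53, 8.15 and 9.64 in cortex and 4.86, 6.59, 7.56 and 8.60 in medulla. Its range was 2.67 without cortex replicate 4 and 2.00 without medulla replicate 1, against 4.17 and 3.73. Clusterin (Clu) ranged over 3.31 log2 units in cortex and 3.59 in medulla, the protease gene Adamts1 over 3.31 and 3.39, the cytokine gene Lif over 3.07 and 3.46, and the metalloproteinase inhibitor gene Timp1 over 2.97 and 3.38. Without cortex replicate 4 the cortex ranges were 1.35 for Clu, 0.73 for Adamts1, 0.16 for Lif and 0.13 for Timp1. Without medulla replicate 4 the medulla ranges were 0.95 for Adamts1, 0.93 for Lif and 1.75 for Timp1. With Fga, Fgb and Fgg these are the 10 genes whose smaller regional range was the largest. Spp1 measured 11.64 on cortex replicate 4 against 9.18 to 10.01 on the other cortex arrays, and 9.79 to 11.97 on the medulla arrays. Lcn2 measured 5.44 and 5.82 on the replicate 4 arrays, against 4.70 to 4.83 on the other cortex arrays and 4.76 to 4.83 on the other medulla arrays. Umod had its lowest values on the replicate 4 arrays, 10.73 in cortex and 10.54 in medulla, against 11.68 to 11.89 on the other cortex arrays and 11.36 to 11.80 on the other medulla arrays.

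**Figure D2:**
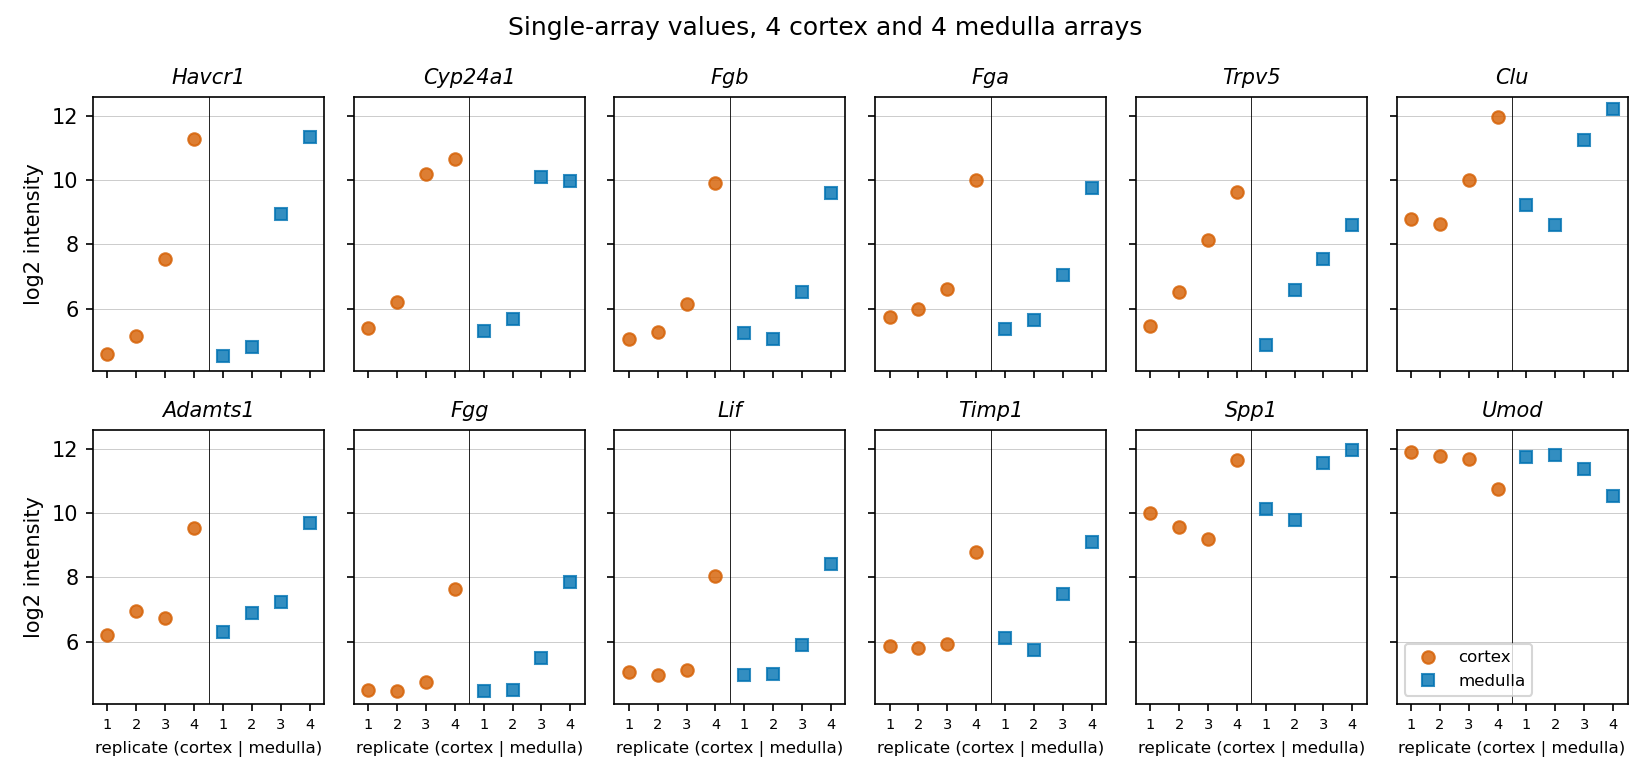
Log2 intensity (vertical axis) of 12 genes on each of the 8 arrays (horizontal axis, replicates 1 to 4 of cortex as orange circles and of medulla as blue squares), 1 point per array and no averages. The replicate numbers only name arrays and pair nothing, and the replicate 4 arrays hold the highest Fga values, 10.01 and 9.75, and the lowest Umod values, 10.73 and 10.54.

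The range reached 2-fold in 654 genes (3.6%) between cortex arrays and in 691 genes (3.8%) between medulla arrays, and 402 genes passed in both regions. Independent lists of these sizes would share 24.9 genes, or 51.8 when drawn within 20 bins of mean expression. Across genes, which are not independent replicates, the ranges of the regions correlated with a Pearson r of 0.799. Cortex replicate 4 was the array farthest from the other 3 in 75.8% of the 654 genes, and medulla replicate 4 in 74.5% of the 691. In 306 of the 402 shared genes the farthest arrays were cortex replicate 4 and medulla replicate 4, above the others in both regions in 157 and below in both in 149, with opposite sides in 0. Without cortex replicate 4 the counts were 145 in cortex and 84 in both regions, and without medulla replicate 4 they were 170 in medulla and 92 in both. With both arrays left out, a setting chosen after the data were seen, 45 genes passed in both regions. Independent lists would share 1.36, a number not matched on mean expression.

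**Figure D3:**
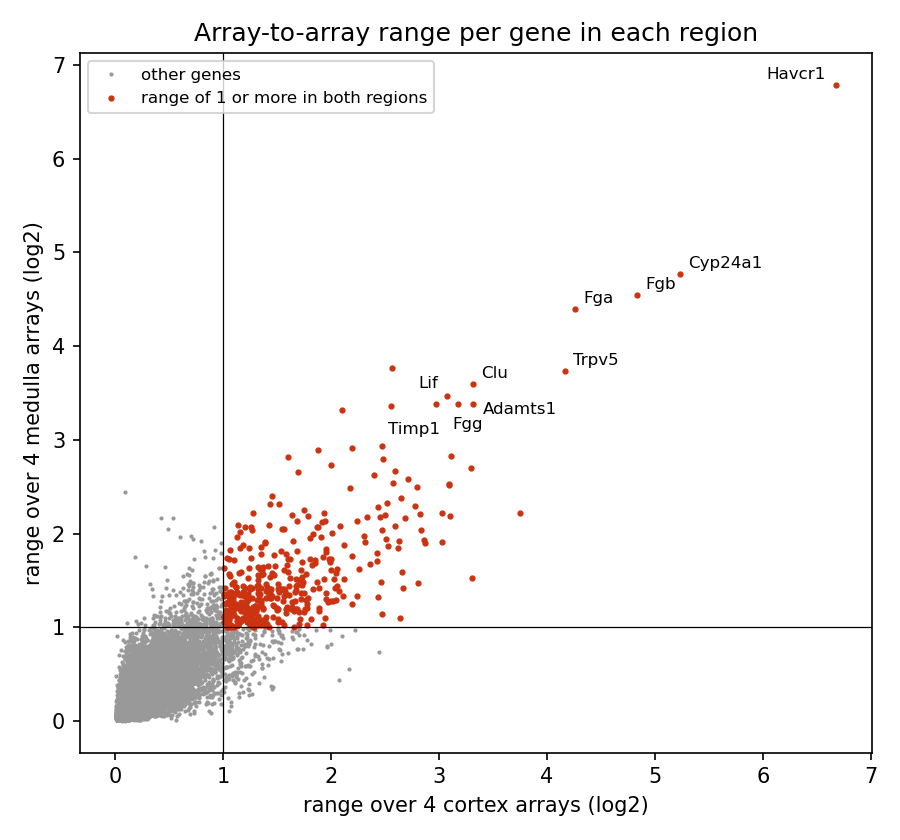
Range over the 4 cortex arrays (horizontal axis, log2) against the range over the 4 medulla arrays (vertical axis, log2) for 18166 genes, 1 point per gene. Lines mark a 2-fold range, red points are the 402 genes past it in both regions, and Havcr1 lies farthest out at 6.68 and 6.79.

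In both regions, the mean deviation was highest on the replicate 4 array for 7 lists, in some of them through a minority of their genes. These were tubular injury, proliferation, fibrinogen and coagulation, stone matrix proteins, leukocytes, chemokines and oxidative stress. It was lowest there for 7 lists, namely the thick ascending limb, collecting duct principal cells, intercalated cells, the proximal straight tubule, endothelium, urothelium and adipocytes. The proximal tubule list is in neither set. Its mean deviation was 0.25 on cortex replicate 4 and -0.05 on medulla replicate 4, with 7 of 22 genes highest and 8 lowest on both of these arrays. The deviations of these 2 arrays correlated at 0.845 over all genes, so many genes outside the lists are extreme on both too. Their share is not given here, so the counts of members below do not by themselves set a list apart. In the tubular injury list 13 of 19 genes passed a 2-fold range in both regions, and its mean deviation from the region's mean was 0.98 on cortex replicate 4 and 0.99 on medulla replicate 4, with 13 of 19 genes highest on both of these arrays. The proliferation list deviated by 0.62 and 0.84 there, with 9 of 9 genes highest on both, and its topoisomerase gene Top2a measured 6.68 on cortex replicate 4 against 5.23 to 5.65 on the other cortex arrays. The thick ascending limb list had 8 of 13 genes past 2-fold in both regions, with mean deviations of -0.55 and -0.38 on those arrays, and its sodium, potassium and chloride cotransporter gene Slc12a1 measured 8.62 on cortex replicate 4 and 10.15 on medulla replicate 4 against values from 10.42 to 11.26 on the other 6 arrays. In this list 9 of 13 genes were lowest on both arrays and 2 were highest on both, the prostaglandin receptor gene Ptger3 at 9.06 and 9.65 and the claudin gene Cldn19 at 7.99 and 9.16. The collecting duct principal cell list deviated by -0.43 and -0.63, with 7 of 12 genes lowest on both. Endothelium deviated by -0.43 and -0.35 (7 of 9 genes lowest on both), the proximal straight tubule by -0.60 and -0.36 (4 of 6) and intercalated cells by -0.32 and -0.54 (7 of 12). The leukocyte list deviated by 0.13 and 0.26, with 7 of 19 genes highest on both, and by 0.11 on cortex replicate 1. The other lists named above moved less than tubular injury, and in some the mean rested on a minority of their genes. Fibrinogen and coagulation had means of 0.64 and 0.55 but medians of 0.098 and 0.074, with 7 of 16 genes highest on both and 2 lowest. Stone matrix proteins had means of 0.26 and 0.23 but medians of 0.048 and 0.024 (6 of 17 highest, 1 lowest). Chemokines had means of 0.31 and 0.25 (7 of 14 highest) and oxidative stress 0.11 and 0.10 (4 of 16 highest, 3 lowest). Urothelium had means of -0.06 and -0.23 (2 of 7 lowest), with -0.22 on medulla replicate 2, and adipocytes -0.18 and -0.10 (3 of 7 lowest, 1 highest). In the fibroblast and extracellular matrix list 7 of 12 genes passed in both regions, with fibronectin (Fn1) between 7.06 and 8.71 in cortex and between 7.78 and 9.69 in medulla. In the fibrinogen and coagulation list 4 of 16 passed in both.

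The mean of the vitamin D and calcium handling list was lowest on the replicate 1 array and highest on the replicate 3 array of each region, but its genes did not share 1 order. The vitamin D and calcium handling list had 5 of 15 genes past 2-fold in both regions, and its mean deviations were -0.57, -0.08, 0.48 and 0.17 on cortex replicates 1 to 4 and -0.41, 0.11, 0.30 and 0.003 on medulla replicates 1 to 4. Of its 15 genes, 2 were highest on both replicate 4 arrays, among them Trpv5, and 5 were lowest on both, among them the calcium-sensing receptor gene Casr, at 6.48 on each, which was chosen after its values were seen. The vitamin D receptor gene Vdr measured 7.46, 8.12, 8.86 and 8.69 on the cortex arrays and 7.37, 7.93, 8.03 and 8.04 on the medulla arrays. The distal convoluted and connecting tubule list had 5 of 9 genes past 2-fold in both regions, and the sodium and calcium exchanger gene Slc8a1 measured 7.64, 8.88, 9.26 and 7.59 in cortex and 7.17, 8.47, 8.48 and 6.96 in medulla. Against 10000 random lists matched on expression, the median range of 15 of the 26 lists lay at or above the 95th percentile in both regions, which describes these arrays and is no test. The proximal tubule list (4 of 22 in both regions), collecting duct principal cells (5 of 12), intercalated cells (4 of 12) and proliferation (2 of 9) were among the 15, while fatty acid oxidation (0 of 12) and glycolysis and hypoxia (0 of 10) were not.

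**Figure D4:**
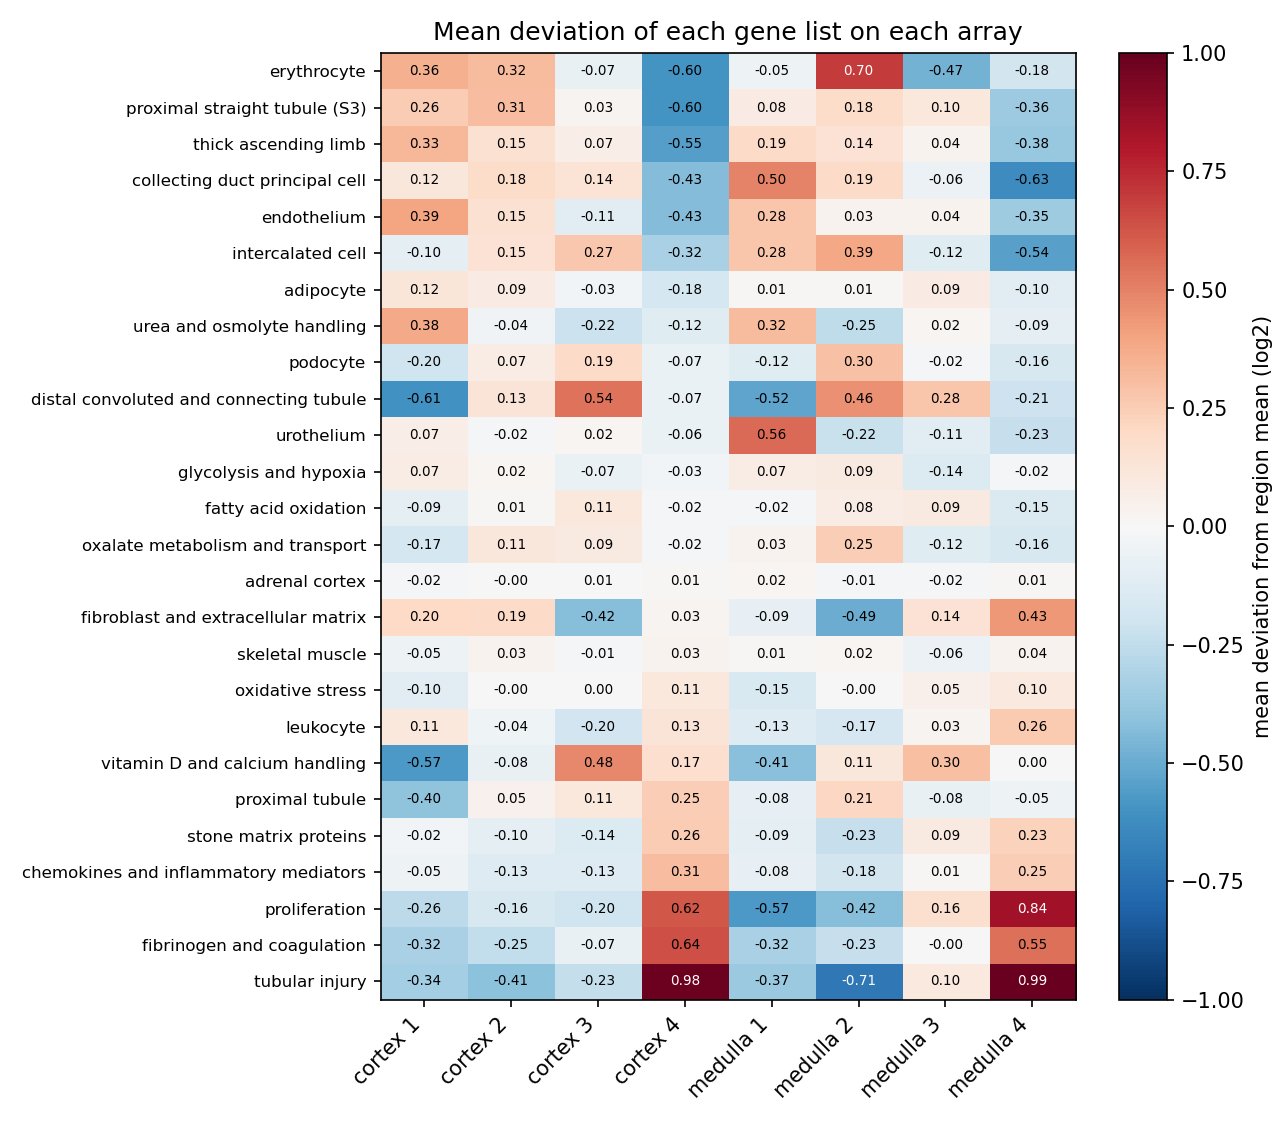
Mean deviation of each gene list (vertical axis) on each array (horizontal axis) from the mean of the 4 arrays of its region, in log2 units, by colour and printed in each cell. The tubular injury list stands at 0.98 on cortex replicate 4 and 0.99 on medulla replicate 4.

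The arrays of the regions also resembled each other across all genes. Each array's deviation from its region's mean was correlated across 18166 genes with each array of the other region, 16 values in all, with no test because genes are not independent. The highest was 0.845, between cortex replicate 4 and medulla replicate 4. Cortex replicate 2 with medulla replicate 2 gave 0.552, cortex replicate 1 with medulla replicate 1 gave 0.502, and cortex replicate 3 with medulla replicate 2 gave 0.467. Cortex replicate 3 with medulla replicate 3 gave 0.03, and the lowest was -0.659, between cortex replicate 2 and medulla replicate 4. Deviations sum to 0 within a region, so the 16 values are not independent. A strong shared deviation of the replicate 4 arrays pushes the other arrays the opposite way in both regions. Positive values among those others, and negative values with a replicate 4 array, are therefore in part built in. The numbers follow the order of the labels, and no pairing of arrays was drawn from these values.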

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

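The tests of explanations in this part were chosen only after the results were seen. For each of the 56 genes named in the text, the gap between the array farthest from the rest and its nearest neighbour was divided by the region's range. In 19 of 112 sets of 4 arrays this ratio was unusually large, where chance gives about 1 in 20, or 5.6. Over all genes the ratio was as large in 7.88% in cortex and 6.45% in medulla. The genes are not independent, and some were named because they varied. Cortex replicate 4 stood apart above the other cortex arrays in Fgg (ratio 0.904, log2 level 7.64), Lif (0.948, 8.05), Timp1 (0.957, 8.78), Lcn2 (0.834, 5.44), Lgals3 (0.937, 6.85), Osmr (0.881, 9.06), Socs3 (0.926, 7.51), Myc (0.911, 8.35) and Atf3 (0.942, 8.01). It stood apart below them in Casr (0.917, 6.48) and Dnase1 (0.839, 6.98). Medulla replicate 4 stood apart above the other medulla arrays in Lcn2 (0.935, 5.82), Myc (0.858, 8.29) and Atf3 (0.842, 7.73), and below them in Slc12a1 (0.839, 10.15) and Slc16a7 (0.977, 7.98). Cortex replicate 1 stood above in Slc5a3 (0.919, 8.12), medulla replicate 1 below in Vdr (0.844, 7.37), and medulla replicate 3 above in Alb (0.88, 4.59), whose whole medulla range was only 0.08 log2.

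The first pattern is the range of the fibrinogen chains, over 8-fold within each region. RNA of liver, the main source of fibrinogen, would bring its other abundant transcripts, but the 18 measured genes of a hepatocyte list had median ranges of 0.162 and 0.159 log2 in cortex and medulla, and albumin (Alb) stayed at or below 4.59 on every array. Of the 18 genes, 9 also belong to other lists here, 3 lay above the median probe set on all arrays, and the 9 not seen before the list was written had median ranges of 0.153 and 0.151. The 500 genes nearest to each chain in mean signal had a median deviation of at most 0.022 on the replicate 4 arrays, where Fga deviated by 2.92 and 2.79. Values normalized to nearly equal quartiles hold such a median near 0, so it cannot decide on an effect of normalization. Of these 500 genes, 0 rose as far above the mean of their region as the chain did, for each chain on both arrays. No biological explanation was tested, since no labelled group divides the arrays of a region, and transcription of these genes in the kidney may be a source but remains a hypothesis.

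The second pattern is that cortex replicate 4 and medulla replicate 4 deviate together. Exchanged region labels of these arrays would make the urea and osmolyte list lower on medulla replicate 4, but its median was 0.652 log2 higher there than on cortex replicate 4. Leukocyte RNA as the whole source of the deviation would move leukocyte genes at least as far as the injury list. The leukocyte list's mean deviation minus that of the injury list was -0.856 on cortex replicate 4 (SE over genes 0.251) and -0.729 on medulla replicate 4 (SE over genes 0.222). These SE measure the spread over genes on 1 array, and the genes are not independent replicates. A rise of dim leukocyte genes may be understated, so leukocytes as the whole source are not excluded. Effects of leukocytes on the genes of other cells are not addressed by this comparison. The leukocyte list was itself highest on these arrays, at 0.127 and 0.261 (though also at 0.108 on cortex replicate 1), so leukocytes as a part of the cause stay open. Another candidate explanation that stays open is that the shared treatment label does not describe every array, since Cyp24a1, which vitamin D induces, ranged over at least 4.77 log2 in each region, but unequal responses to the same treatment would give such a range too, so these cannot be told apart, and a shared animal, a shared processing day and RNA quality were not tested.

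The third pattern is that lists were called between the regions while 0 genes were, a count below which no split can fall, so the 35 splits of the arrays into 4 and 4 (highest other 1) say nothing about chance for genes. Chance is not excluded for the 11 called lists, since 4 of the 35 splits gave at least as many, up to 13. The split of cortex replicates 1, 2 and 3 with medulla replicate 2 against the rest reached an unadjusted p under 0.05 in 2689 genes. The real split reached it in 971. The former exchanges only cortex replicate 4 and medulla replicate 2, keeps the replicate 4 arrays together, and points to a structure other than the region labels. In mean deviation, medulla replicate 2 leaned toward cortex (0.456 for the distal list, -0.254 for urea) and cortex replicate 1 toward medulla (-0.606 and 0.375). Of the called lists, endothelium (0.034) on the first and tubular injury (-0.336) on the second lay the other way. Over all probe sets cortex replicate 1 correlated at 0.9934 with medulla replicate 1 and 0.9935 with medulla replicate 2. Its highest value with another cortex array was 0.9925, with cortex replicate 2. Cortex replicate 3, by contrast, correlated most with cortex replicate 2, at 0.9937. Mixing of the regions in the tissue was not tested, so the 0 called genes do not show that cortex and medulla are alike. With 3 residual components as covariates 733 genes passed the adjusted p for region at any fold. Of the 35 splits treated alike 17 gave as many, up to 3448. The highest counts came from splits with cortex replicate 4 and medulla replicate 4 on the same side, which the real split separates. The number of splits therefore does not measure chance alone. Among the other splits that separate these arrays, cortex replicate 1 with medulla replicates 1, 3 and 4 gave 2341, and the rest 327 or fewer. Chance is not excluded there either. A difference of region in single genes may be hidden by that structure, and the counts with covariates do not settle it.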

How the results depend on the processing

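The residual components and the setting with both replicate 4 arrays left out were chosen after the data were seen. No paired analysis was possible because the labels name no animal and no number shared by a cortex and a medulla array. Signal over background limits genes near the lowest intensities, whose folds are understated. Under the planned settings other than a left-out replicate, 196 of 198 values of the 33 region differences kept their direction and their side of the threshold. The exceptions were Fgb at -0.001 with quantile normalization, whose cause was not tested, and Havcr1 at -0.21 with array weights. The weights were lowest on arrays with high Havcr1, at 0.535 on cortex replicate 4, 0.513 on medulla replicate 3 and 0.563 on medulla replicate 4. The other arrays had weights from 1.113 to 2.033, and this weighting turned the sign for Havcr1. The trended robust prior and the filter on dim genes cannot change the size of a difference. Nor can the mean of probe sets for a gene with a single probe set, which each of the 115 named genes has. For those genes only quantile normalization, median centring and array weights tested the difference. All 80 recomputed ranges of the 10 most variable genes moved by less than 1 SD under those settings. For these genes, each with a single probe set, the filter and the mean of probe sets cannot change a range. Only quantile normalization and median centring tested it. With the estimated correlation 0 lists were called, and the cause was not tested; the other planned settings for lists, replicates apart, called 11 to 13.

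With each replicate left out in turn, 0 genes were called each time and 5 to 13 lists. Genes over 2-fold ranged from 145 to 654 in cortex, from 170 to 691 in medulla and from 84 to 379 in both, where fewer arrays can only narrow a range. The difference between medulla and cortex ranged from -1.07 to 0.83 for Fga, -0.98 to 1.11 for Fgb, -0.52 to 1.01 for Fgg, -1.04 to 1.64 for Havcr1, -1.25 to 0.49 for Cyp24a1, -0.15 to 0.28 for Lcn2 and -0.42 to 0.12 for Umod. With cortex replicate 4 and medulla replicate 4 both left out, 5 lists were called, and 145 genes in cortex, 170 in medulla and 45 in both regions passed 2-fold. A 3-fold range gave 186, 157 and 96 genes, and a 1.5-fold range 2063, 2738 and 1475. A 2-fold difference of the regions with no test gave 16 genes, all 16 higher in medulla. With 1 or 2 residual components as covariates 0 genes were called, and with 3 components 10, all 10 higher in medulla. The components come from what remained after fitting region, so they cannot change a difference and act only through its standard error. The Slc14a2 difference stayed at 1.534, while its standard error went from 0.323 to 0.169. These calls are therefore no larger differences between the regions.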

Other observations

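The genes of this part outside the lists, and the fits with residual components, were chosen only after the values were seen. Among the 402 genes over 2-fold in both regions, the oncostatin M receptor gene Osmr measured 6.95, 6.86, 6.66 and 9.06 log2 intensity on cortex replicates 1 to 4 and 6.82, 6.70, 7.98 and 9.32 on medulla replicates 1 to 4. Socs3, a feedback inhibitor of cytokine receptors, measured 5.38, 5.49, 5.33 and 7.51 in cortex and 5.51, 5.52, 6.30 and 8.00 in medulla. The early response genes Myc and Atf3 measured 8.35 and 8.01 on cortex replicate 4 and 8.29 and 7.73 on medulla replicate 4, with no other array above 6.08 for Myc or 5.89 for Atf3. Metallothionein gene Mt1, uncertain because it has near-identical copies, measured 9.41, 9.28, 10.66 and 11.71 in cortex and 9.15, 9.15, 10.05 and 11.43 in medulla.

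Other genes were lowest on the replicate 4 arrays. The calcium-sensing receptor gene Casr, of the vitamin D and calcium handling list, measured 6.48 on both, against 8.53 to 8.72 on the other cortex arrays and 8.15 to 8.61 on the other medulla arrays. It too was chosen after its values were seen. The monocarboxylate transporter gene Slc16a7 measured 7.86 and 7.98, against 10.01 to 10.65 and 10.43 to 10.48. The nuclease gene Dnase1 measured 9.54, 9.21, 9.13 and 6.98 in cortex and 9.86, 9.89, 8.25 and 6.13 in medulla. The growth factor gene Igf1 measured 8.69, 7.86, 6.17 and 5.86 in cortex and 8.40, 8.39, 7.21 and 6.36 in medulla, and the lipoprotein lipase gene Lpl 9.25, 8.37, 7.20 and 6.62 in cortex and 8.86, 8.83, 8.10 and 6.95 in medulla.

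Cyp24a1 fell into separate clusters within each region. In cortex 2 arrays measured 5.42 and 6.21 and 2 measured 10.18 and 10.65, and in medulla 2 arrays measured 5.31 and 5.69 and 2 measured 10.08 and 9.97. Fga stood at 6.61 on cortex replicate 3 and 7.04 on medulla replicate 3, where Cyp24a1 measured 10.18 and 10.08, and at 10.01 and 9.75 on the replicate 4 arrays, where Cyp24a1 measured 10.65 and 9.97.

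After fitting region, the first component of the remaining variation held 60.4% of it, with loadings of 0.61 on cortex replicate 4 and 0.58 on medulla replicate 4, and the next components held 16.3% and 11.6%. With 3 components as covariates limma called 10 genes, all higher in medulla, among them Slc14a2 (adjusted p = 0.0235), Slc5a3 (0.0252) and Slc14a1 (0.0455) of the urea and osmolyte list. In the same fit 17 of the 35 splits of the arrays called at least 10 genes, up to 101. The highest counts came from splits with the replicate 4 arrays on the same side, unlike the real split. Cortex replicate 1 with medulla replicates 1, 3 and 4, a split that separates them, called 28. These p-values can therefore not be taken as calibrated. Among the 11359 probe sets with no single gene name, 108 passed a 2-fold range in cortex, 267 in medulla and 65 in both; their genes were not analysed here.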
